A study of Solanum commersonii and Solanum tuberosum with 8 samples.

How the data were processed

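Leaf RNA of Solanum commersonii, a wild potato that tolerates freezing, and of Solanum tuberosum, the cultivated potato, was compared on 2-colour microarrays. Per the labels' protocols, plants were grown for 3 weeks at 25°C with 16 h of light and 8 h of darkness, and cold began 8 h after dawn at 2°C. The labels give a light intensity of 50 for the cold plants and 350 for the warm controls, in the same unit, so light changed together with temperature. The 2 h cold plants were compared with wild-type plants kept warm for 2 h, and the 24 h and 7 d cold plants with wild-type plants kept warm for 24 h. The 7 d plants were therefore older than their controls. Plants carrying 35S::AtCBF3, a constitutive promoter driving the Arabidopsis transcription factor CBF3, were compared with wild-type plants in the warm. They came from 3 independent S. commersonii lines and 2 S. tuberosum lines, and the cold treatments from 3 independent experiments. The genotype field of the S. tuberosum transgenic sample names S. commersonii, while its title, source name and organism name S. tuberosum, and it was treated as S. tuberosum.

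The authors deposited 1 ratio value per clone and column, in 8 columns of 11366 clones with no missing value. Each deposited log2 ratio combines the slides of a sample, 3 per column and 2 for S. tuberosum 35S::AtCBF3, per the labels' descriptions. Per the labels, RNA was labelled with Cy3 and Cy5 by an indirect aminoallyl method, and each channel of a sample lists both dyes. An odd number of slides cannot balance the dyes, so a dye effect of a clone can remain in the columns made from 3 slides. limma was used, per the submitters' processing notes; background correction, normalization within and between slides, spot filters and the way slides were combined are not given in the sources used here. The log base, the direction of the ratio and any centring are also not stated. The values were read as log2 because limma works on that scale, and the column medians lay between -0.0075 and 0.011. The labels place the cold or transgenic RNA in channel 1 and the warm wild type in channel 2 of every sample, and the design text compares the treated plants with the warm ones, so a positive ratio was taken as higher in the cold or transgenic plants. This direction is likely, not settled, and the marker lists fixed as a check on it could not be matched to clones. The lowest correlation between any pair of columns across clones was -0.0095.

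The values per slide were not analysed here. There is thus no spread between replicates, and no standard error, p-value or test between conditions was computed; leaving out a slide and any replicate block were not possible. Results are sizes and counts. A clone was counted as higher or lower when its ratio was at least 2-fold, a log2 ratio of 1 or more in size. Most counts shared by 2 columns are given beside the number that independent lists of the same sizes would share. Shares carry exact Clopper-Pearson 95% intervals, and differences between sets of clones carry 95% intervals from 1000 resamplings of clone-name blocks, the sets of clones that share the first 5 characters of their names. Both describe clones, not plants. Clones are not independent, since several can carry the same gene. Signal intensities were not analysed here, so dim clones could not be set apart and the number of slides limits the precision.

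The clones are named only by identifiers such as STMHH62, and no gene names were matched to them here. The 49 gene lists, the averaging of clones of 1 gene and the marker checks fixed before the data were examined were therefore not run, and each clone was kept as 1 value. By the rule fixed for that case, at most 2 clones that were higher and 2 that were lower are named. They are the highest and lowest by the mean of the 6 cold columns, a ranking chosen after the table had been seen. The level of the transgene could not be checked for the same reason.

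The columns for 24 h and 7 d of cold share a warm control within each species. Unchanged columns with a shared control were simulated 100 times. The whole central spread of each column (from the median absolute deviation) was taken as noise. The control and the cold RNA had equal variances in the 24 h column, which had the smaller spread. The rest of the variance of the 7 d column was given to its cold RNA. Whether the wild-type RNA set against the 35S::AtCBF3 plants was that of the cold experiment is not stated. Counting was tested on simulated data with 200 changed clones among 11366: for the pair of 2 h columns, 98% of clones raised 3-fold in both were counted in both, and for the pair of 35S::AtCBF3 columns 86%. Of clones raised exactly 2-fold, 23% and 25% were counted in both columns. Alternatives were thresholds of 1.5-fold and 3-fold, columns centred on their median, columns scaled to one spread, and other definitions of a difference between species. Subtraction of block means and removal of the clones higher at 2 h were added after the data had been seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.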

Results

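The response of leaf transcripts to cold and to constitutive expression of Arabidopsis CBF3 was measured in S. commersonii and S. tuberosum with 11366 array clones. CBF3 is a transcription factor that activates cold-responsive genes in Arabidopsis. There were 8 columns of log2 ratios. Each species had 1 column for 2 h, 1 for 24 h and 1 for 7 d of cold at 2°C, and 1 for 35S::AtCBF3 plants in the warm, each against warm wild type. Every column held 1 value per clone combined from 3 slides, or from 2 slides for S. tuberosum 35S::AtCBF3, and so carries no error of its own. A difference between columns could therefore not be set against a spread between replicates. Most clones differed little from the control: the central spread of the log2 ratios (SD from the median absolute deviation) was 0.22 at 2 h in both species. This spread was 0.29 in S. commersonii and 0.37 in S. tuberosum at 24 h, and 0.38 and 0.43 at 7 d. In the 35S::AtCBF3 columns it was 0.37 in S. commersonii and 0.48 in S. tuberosum, the column with the fewest slides. Ratios are described as higher or lower in the cold or transgenic plants, the likely direction from the labels.

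The first question was how many transcripts differed after each time in the cold. At 2 h the change was almost wholly upward. In S. commersonii 1241 clones were at least 2-fold higher and 17 lower, and in S. tuberosum 895 were higher and 38 lower. At 24 h the species stood apart, with 301 clones higher and 141 lower in S. commersonii and 1354 higher and 163 lower in S. tuberosum. By 7 d lower clones outnumbered higher ones in both species, with 352 higher and 616 lower in S. commersonii and 459 higher and 730 lower in S. tuberosum. Higher clones made up 98.6% of the changed clones at 2 h, 68.1% at 24 h and 36.4% at 7 d in S. commersonii. The corresponding shares in S. tuberosum were 95.9%, 89.3% and 38.6%. If the ratios ran the other way, every higher clone would be a lower one. A normal distribution with the central spread of each column would put at most 0.063 clones above 2-fold at 2 h, and 117 above and 128 below at 7 d in S. tuberosum, the cold column with the largest spread.

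**Figure D1:**
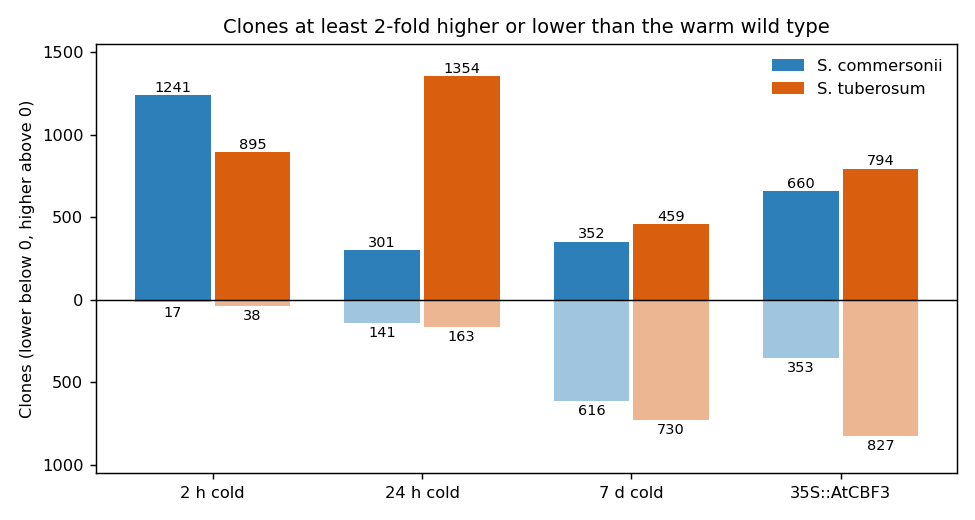
Number of clones (y axis) at least 2-fold higher (solid bars above 0) or lower (pale bars below 0) than the warm wild type in each column (x axis), for S. commersonii (blue) and S. tuberosum (orange); each column is 1 deposited value per clone, without error bars. At 24 h S. tuberosum has 1354 higher clones and S. commersonii 301, while at 7 d lower clones (616 and 730) exceed higher ones in both.

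The clones with the highest mean over the 6 cold columns were STMHH62 and STMFB08. STMHH62 had log2 ratios of 4.93, 2.77 and 1.54 at 2 h, 24 h and 7 d in S. commersonii, and of 3.74, 4.46 and 0.49 in S. tuberosum. STMFB08 increased with time in the cold instead, with 1.32, 2.43 and 2.46 in S. commersonii and 1.91, 3.35 and 4.02 in S. tuberosum. Its log2 ratio in 35S::AtCBF3 plants was 3.51 in S. commersonii and 2.43 in S. tuberosum. The lowest means were those of STMCR06 and STMIG06. STMCR06 was at -2.47 after 7 d in S. commersonii and at -3.69 in S. tuberosum, and STMIG06 at -3.55 and -2.73. With 35S::AtCBF3 in S. tuberosum these clones were at -4.81 and -5.45, and in S. commersonii at -0.51 and -1.74. A set of 12 clones was at least 2-fold higher in all 6 cold columns, and 10 of the 12 were also at least 2-fold higher in each 35S::AtCBF3 column, where independent lists would give 0.697 in S. commersonii and 0.838 in S. tuberosum. The other 2 clones were at least 2-fold lower with 35S::AtCBF3 in S. commersonii. No clone was 2-fold lower in all 6 cold columns.

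The time course was followed with clone classes. The clones higher at 2 h behaved differently in the 2 species at 24 h. Of the 895 clones higher at 2 h in S. tuberosum, 774 were still higher at 24 h (86.5%, 95% interval 84.1 to 88.7%), against 107 for independent lists. Of the 1241 clones higher at 2 h in S. commersonii, 125 were (10.1%, 8.45 to 11.9%), against 32.9. The S. commersonii share depended on the threshold and was 37.2% at 1.5-fold, 1.33% at 3-fold and 17.2% with the columns scaled to one spread, while that of S. tuberosum lay between 75.5 and 87.8% under these settings. By 7 d, 37 of these clones in S. tuberosum and 34 in S. commersonii were 2-fold higher, against 36.1 and 38.4 for independent lists. Clones changed at 24 h were more often changed the same way at 7 d. In S. commersonii 98 higher and 95 lower clones were shared by 24 h and 7 d, against 9.32 and 7.64 for independent lists. In S. tuberosum the shared numbers were 168 and 122, against 54.7 and 10.5. The correlation across clones between 24 h and 7 d was 0.52 in S. commersonii and 0.31 in S. tuberosum, and 0.53 and 0.50 without the 813 clones higher in both species at 2 h. These columns share a warm control, and unchanged columns simulated with it gave correlations of 0.38 and 0.42 and at most 5.24 shared higher clones. In S. tuberosum the correlation over all clones, 0.31, lay below the simulated 0.42. A larger noise variance of the control would give higher simulated correlations. The covariance exceeded the simulated one by 0.094 in S. commersonii and 0.092 in S. tuberosum. The simulated columns held only the central spread, while the observed ones also held the clones in the tails. This excess can partly reflect that difference. The controls could not be split, so the share due to the common control was not measured. Columns of different species share no control. S. commersonii at 24 h and S. tuberosum at 7 d correlated at 0.40, with 96 shared higher and 73 shared lower clones, against 12.2 and 9.06. S. tuberosum at 24 h and S. commersonii at 7 d correlated at 0.32, with 107 and 96, against 41.9 and 8.83. These values argue against the common control as the whole cause. Between 2 h and 7 d, which have separate controls, the correlation was 0.081 in S. commersonii and 0.0056 in S. tuberosum.

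The second question was how the cold response differed between the freezing-tolerant and the cultivated species. At 2 h the species shared 813 higher clones, against 97.7 for independent lists, and the ratios correlated across clones (r = 0.86, Spearman's rho = 0.61). This early class had a median log2 ratio of 2.37 in S. commersonii (5.16-fold) and of 1.53 in S. tuberosum (2.89-fold) at 2 h. At 24 h its median was 0.63 in S. commersonii (1.55-fold), with 107 of the 813 clones at least 2-fold higher, and 2.40 in S. tuberosum (5.27-fold), with 752 of the 813. In S. commersonii 798 of the 813 still had ratios above 0 at 24 h. At 7 d the class stood at 0.10 in S. commersonii and -0.12 in S. tuberosum. A total of 1039 clones were at least 2-fold higher in S. tuberosum than in S. commersonii at 24 h, and 64 were higher in S. commersonii. The early class supplied 711 of the 1039 clones (68.4%), leaving 328 outside it. With the columns scaled to one spread, 942 clones were higher in S. tuberosum and 89 in S. commersonii. When a slope fitted on S. tuberosum was also removed, the counts were 114 and 142. That fit takes out all that scales with S. tuberosum, whether from a single factor between the columns or from a difference between the species. The loss of the imbalance therefore cannot tell these apart, though the fit does not force equal counts. At 2 h 434 clones were at least 2-fold higher in S. commersonii than in S. tuberosum and 23 the reverse, and 245 of the 434 were in the early class. These counts were 1021 and 114 with scaling, 746 and 196 with the slope removed as well, and 202 and 40 for clones changed 2-fold in one species and under 1.5-fold in the other.

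**Figure D2:**
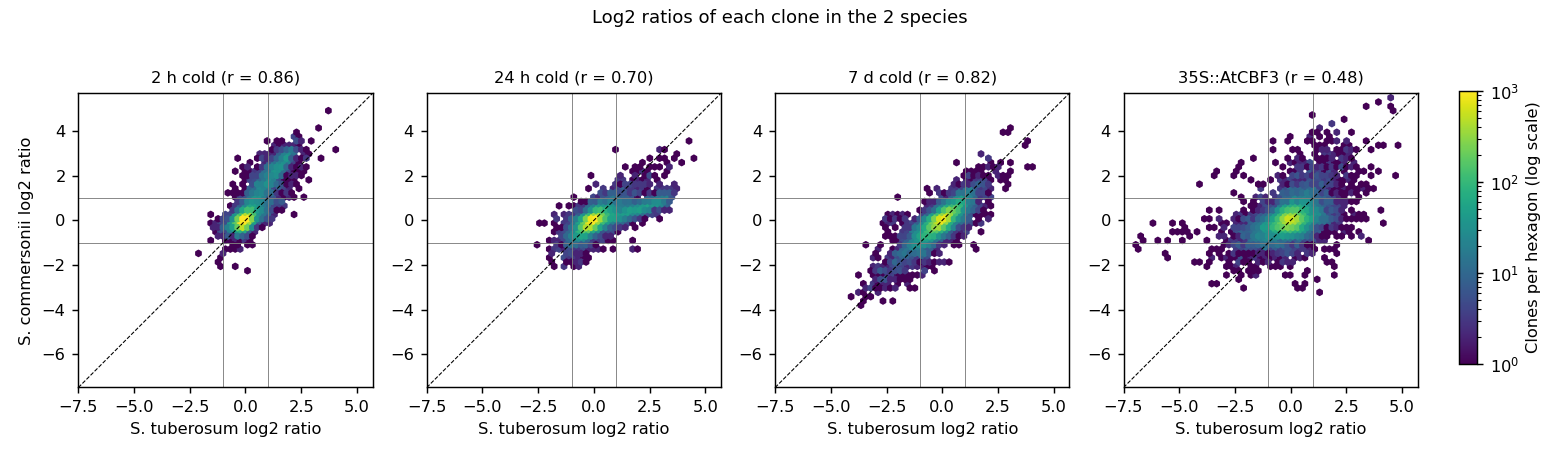
Log2 ratio of each clone in S. tuberosum (x axis) and S. commersonii (y axis) for the cold times and for 35S::AtCBF3, with colour giving the number of clones per hexagon on a log scale, grey lines at 2-fold and a dashed line of equality. At 24 h an arm of clones lies high in S. tuberosum and less high in S. commersonii (early-class medians 2.40 and 0.63). At 7 d the points lie along the line of equality (r = 0.82).

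After 7 d the responses of the species were close. They shared 234 higher clones and 440 lower clones, against 14.2 and 39.6 for independent lists, and correlated with r = 0.82 and rho = 0.75. No clone was 2-fold higher in S. commersonii and 2-fold lower in S. tuberosum, and 1 was the reverse. The median log2 ratio of the 440 lower clones was -1.55 in S. commersonii and -1.66 in S. tuberosum. At 24 h these clones were at -0.46 and -0.48, and at 2 h at 0.01 and 0.05. The 234 clones higher at 7 d had medians of 1.42 and 1.40 at that time, of 0.53 and 0.71 at 24 h, and of 0.03 and -0.04 at 2 h. Differences of at least 2-fold between the species at 7 d were found for 129 clones higher in S. commersonii and 145 higher in S. tuberosum. With scaling these were 76 and 89, and at 3-fold the order turned, with 39 and 23. At 24 h the species shared 240 higher and 59 lower clones, against 35.9 and 2.02 for independent lists (r = 0.70).

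**Figure D3:**
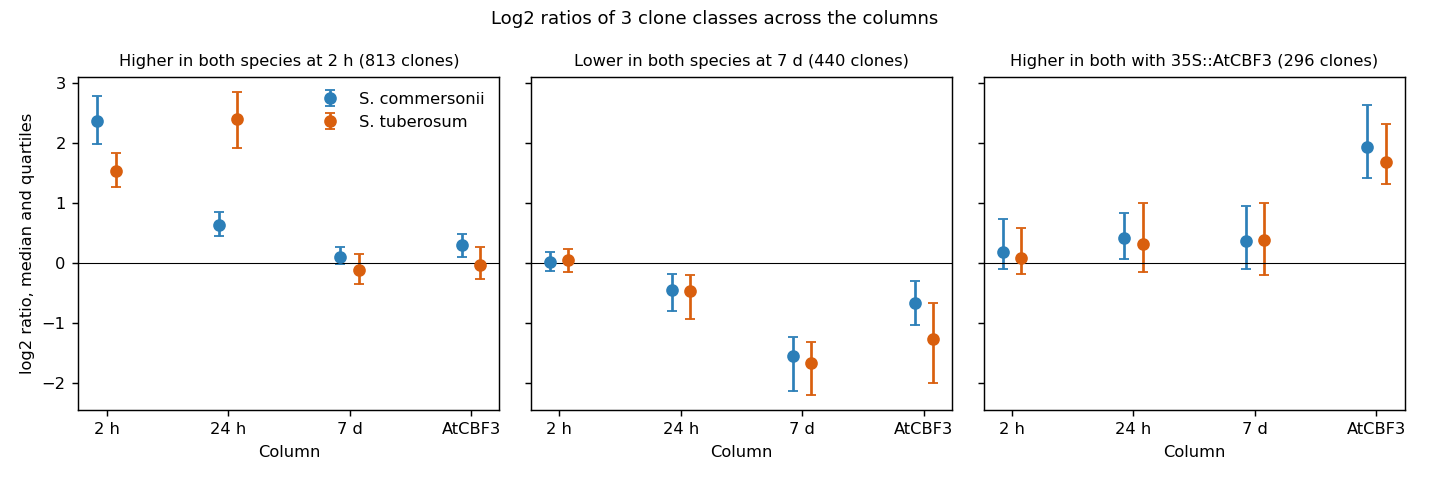
Log2 ratio (y axis; median with lower and upper quartiles over clones, not an error between plants) of 3 clone classes in each column (x axis) for S. commersonii (blue) and S. tuberosum (orange). The 813 clones higher in both species at 2 h stand at 0.63 in S. commersonii and 2.40 in S. tuberosum at 24 h, the 440 clones lower in both at 7 d have negative medians with 35S::AtCBF3 too, and the 296 clones higher in both with 35S::AtCBF3 have medians of at most 0.42 in the cold.

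The third question was what AtCBF3 changed without cold. In S. commersonii 660 clones were at least 2-fold higher and 353 lower in the transgenic plants. In S. tuberosum 794 were higher and 827 lower. The species shared 296 higher clones and 182 lower clones, against 46.1 and 25.7 for independent lists, and correlated with r = 0.48 and rho = 0.40. The 296 shared higher clones had medians of 1.93 in S. commersonii and 1.67 in S. tuberosum, and the 182 shared lower clones had medians of -1.30 and -1.85. A total of 769 clones were at least 2-fold higher in S. commersonii than in S. tuberosum and 612 the reverse, or 536 and 357 with the columns scaled to one spread and 475 and 195 with a fitted slope removed as well. The S. tuberosum column had the larger central spread, and a normal distribution of that spread would put 222 clones above and 202 below 2-fold, against 42.7 and 36.9 in S. commersonii. With all columns scaled to one spread, 593 clones were higher and 292 lower in S. commersonii and 435 and 456 in S. tuberosum, so that the order of the species by higher clones turned.

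The fourth question was which part of the cold response was also seen with AtCBF3 in the warm. Clones lower after 7 d of cold were often lower with 35S::AtCBF3 as well. In S. commersonii 153 of the 616 clones lower at 7 d were also lower with 35S::AtCBF3 (24.8%, 95% interval 21.5 to 28.4%), and in S. tuberosum 398 of 730 (54.5%, 50.8 to 58.2%). At 3-fold the S. commersonii share was 10.1% and at 1.5-fold 35.8%. Relative to independent lists, which would share 19.1 and 53.1 clones, the shared numbers were 8.00 and 7.49 times as large. Of the clones higher at 7 d, 105 of 352 in S. commersonii (29.8%, 25.1 to 34.9%) and 151 of 459 in S. tuberosum (32.9%, 28.6 to 37.4%) were also higher with 35S::AtCBF3, against 20.4 and 32.1 for independent lists. The 24 h columns shared 99 higher clones with 35S::AtCBF3 in S. commersonii, against 17.5 for independent lists, and 136 in S. tuberosum, against 94.6. Lower clones shared with 24 h numbered 34 in S. commersonii, against 4.38, and 57 in S. tuberosum, against 11.9. With 35S::AtCBF3 the early class had a median log2 ratio of 0.29 in S. commersonii, where 688 of its 813 clones were above 0, and of -0.04 in S. tuberosum, where 370 were. At least 2-fold higher were 70 (8.61%) and 66 (8.12%) of them, against 5.81% and 6.99% of all clones. Over all 3 times, 206 of the 1661 clones higher in the cold in S. commersonii were higher with 35S::AtCBF3 (12.4%), and 258 of 1759 in S. tuberosum (14.7%), against 96.5 and 123 for independent lists. For lower clones these numbers were 162 of 673 (24.1%) and 402 of 791 (50.8%), against 20.9 and 57.6. Across clones, 35S::AtCBF3 correlated with 7 d of cold at 0.35 in S. commersonii and 0.47 in S. tuberosum, with 24 h at 0.36 and 0.079, and with 2 h at 0.14 and 0.044. These correlations, among 28 pairs of columns, are across clones, which are not independent replicates. A total of 145 of the 296 clones higher in both transgenic columns were not 2-fold higher in any cold column. Of all 11366 clones, 1661 in S. commersonii and 1759 in S. tuberosum were higher at some time in the cold. The 296 clones were thus higher in some cold column more often than clones in general.

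**Figure D4:**
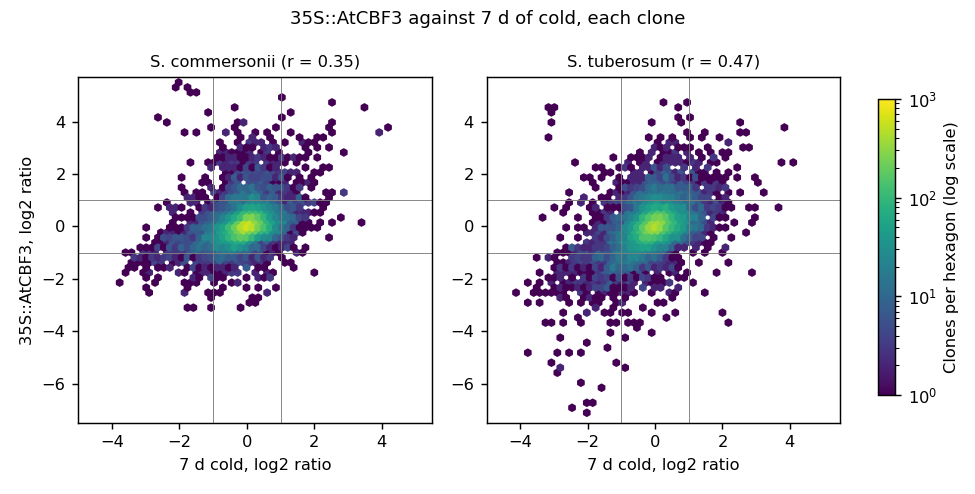
Log2 ratio of each clone after 7 d of cold (x axis) and with 35S::AtCBF3 in the warm (y axis) in S. commersonii (left) and S. tuberosum (right), with colour giving clones per hexagon on a log scale and grey lines at 2-fold. The lower left corner, lower in both, holds 153 clones in S. commersonii and 398 in S. tuberosum.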

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

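The tests in this part were chosen after the values had been seen. With 35S::AtCBF3, 21 clones were at least 2-fold higher in S. commersonii and 2-fold lower in S. tuberosum, and 15 clones were the reverse. Independent lists would give 48.0 and 24.7, so these opposite calls were fewer than for independent lists. At 24 h of cold 3 clones were 2-fold lower in S. commersonii and 2-fold higher in S. tuberosum, against 16.8 for independent lists. At 7 d 1 clone was, against 24.9. These opposite calls in the cold were also fewer than for independent lists. With 1 value per column the difference between the species was not tested for any of these clones.

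From 2 h to 24 h the median of the early class rose from 1.53 to 2.40 in S. tuberosum. In S. commersonii it fell from 2.37 to 0.63. A S. tuberosum 24 h column made wholly of 2 h material is argued against by the 141 clones lower in S. commersonii at 24 h. Their median was -0.90 in the S. tuberosum 24 h column and -0.28 in its 2 h column, a difference of -0.62 (95% interval -0.75 to -0.48). A column in which only some slides held 2 h material is not excluded by this. Over all clones the S. tuberosum 24 h column correlated at 0.82 with S. commersonii at 2 h, 0.74 with S. tuberosum at 2 h and 0.70 with S. commersonii at 24 h. Compression of the whole S. commersonii 24 h column by a single factor was not settled by clones chosen at 7 d. The ratio of the median of S. commersonii to that of S. tuberosum at 24 h was 0.97 (0.84 to 1.07) in the clones lower in both species at 7 d. It was 0.75 (0.53 to 0.86) in those higher at 7 d and 0.26 in the early class. The 7 d columns share the 24 h warm control of their species. Noise of that control could have moved the 24 h medians of clones chosen at 7 d, whatever the compression. The ratio of 0.54 (0.50 to 0.61) in those higher at 24 h carries no weight here, as these clones were chosen on the same columns. Blocks of clones with like names do not account for the gap between the species (whether these were printed together is not known). The 40 of 157 blocks richest in early clones held 43.3% of them, with 25.2% of all clones. Compression of higher clones alone by a single factor was not settled, since the clones higher at 7 d carry the same limit of the shared control. The ratio of 0.75 (0.53 to 0.86) in the clones higher at 7 d lay above that of the early class (0.257 to 0.273). Their S. tuberosum median at 24 h was 0.71, below the 2.40 of the early class. Stronger compression of the highest ratios also stays open. Removing a fitted slope left 142 clones higher in S. commersonii and 114 in S. tuberosum. This cannot tell a single factor between the columns from a difference between the species that scales with S. tuberosum. A difference between the species in when the early response peaks or how long it lasts also stays open and was not tested. So does a signal shared by the early clones whatever gene they carry, such as cross-hybridisation, which cannot be told apart from joint regulation. Within the class, S. commersonii at 2 h and S. tuberosum at 24 h correlated at 0.71. The 2 h columns of the species correlated at 0.59, and S. tuberosum at 2 h and 24 h at 0.35. A shared signal and joint regulation both predict some order kept.

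Clones lower after 7 d of cold were lower with 35S::AtCBF3 more often than independent lists give, in 24.8% of cases in S. commersonii (10.1% at 3-fold) and 54.5% in S. tuberosum (41.8%). A shared warm control is argued against as the whole cause, because columns of different species, which share none, also shared lower clones, at 6.35 times (S. tuberosum cold, S. commersonii 35S::AtCBF3) and 7.14 times (the reverse) the number for independent lists. A spot bias of each clone equal in all columns would have lowered the same clones at 2 h, where their medians lay between 0.040 and 0.073. A dye bias need not have done so and stays open, since the dye balance of each column is not known here. Subtracting the means of clone-name blocks kept 74.5% of the shared lower clones in S. commersonii and 78.1% in S. tuberosum. An effect common to CBF activity and long cold is a candidate explanation that was not tested.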

How the results depend on the processing

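Centring the columns and subtracting block means (the latter chosen after the data had been seen) left each count within 1.5 times its value and each share within its interval. The other settings moved the values below; a lower or higher threshold counts more or fewer clones by construction, and for the rest the cause was not tested. With a 1.5-fold threshold, higher and lower clones in S. commersonii numbered 1617 and 89 at 2 h, 1030 and 536 at 24 h, 1073 and 1357 at 7 d, and 1295 and 1000 with 35S::AtCBF3. In S. tuberosum they numbered 1358 and 184, 1947 and 660, 1315 and 1573, and 1679 and 1623. With a 3-fold threshold the numbers were 902 and 5, 74 and 32, 79 and 248, and 313 and 95 in S. commersonii, and 369 and 2, 903 and 27, 110 and 299, and 311 and 342 in S. tuberosum. Scaling the columns to one spread gave 56 lower clones at 2 h and 482 higher and 236 lower at 24 h in S. commersonii. In S. tuberosum it gave 138 lower at 2 h, 243 higher and 481 lower at 7 d, and 435 higher and 456 lower with 35S::AtCBF3. Clones higher in S. commersonii than S. tuberosum, and the reverse, numbered 1177 and 147 at 2 h, 336 and 1613 at 24 h, 554 and 561 at 7 d, and 1843 and 1541 with 35S::AtCBF3 at 1.5-fold. At 3-fold they numbered 69 and 4, 17 and 542, 39 and 23, and 296 and 192. Scaling gave 1021 and 114 at 2 h, 89 and 942 at 24 h, 76 and 89 at 7 d, and 357 higher in S. tuberosum with 35S::AtCBF3. Counting clones 2-fold in one species and under 1.5-fold in the other gave 202 and 40 at 2 h and 668 higher in S. tuberosum at 24 h. Scaling and removing a fitted slope gave 746 and 196, 142 and 114, 71 and 89, and 475 and 195. The excess in S. tuberosum at 24 h thus stayed with scaling. Its loss with the slope was not forced, since 746 and 196 stayed at 2 h after the same fit. The fit takes out what varies with S. tuberosum, whatever the cause, so the loss does not tell the cause. Without the early class (chosen after the data had been seen), 189 clones were higher in S. commersonii at 2 h and 328 in S. tuberosum at 24 h. The share of 2 h clones still higher at 24 h was 37.2% in S. commersonii and 82.5% in S. tuberosum at 1.5-fold, 1.33% in S. commersonii at 3-fold, and 17.2% and 75.5% with scaling. The share of 7 d lower clones also lower with 35S::AtCBF3 was 35.8% in S. commersonii at 1.5-fold, 10.1% there and 41.8% in S. tuberosum at 3-fold, and 43.5% in S. tuberosum with scaling. For 7 d higher clones it was 39.2% in S. commersonii at 3-fold and 26.7% in S. tuberosum with scaling. If the ratios ran from warm to cold, the share of changed clones that were higher would be 1.35, 31.9 and 63.6% at 2 h, 24 h and 7 d and 34.8% with 35S::AtCBF3 in S. commersonii, and 4.07, 10.7, 61.4 and 51.0% in S. tuberosum. Averages per gene, gene lists and slides left out were not run, as clones had no gene names and slides no separate values here; the filter for clones measured in all columns removed none.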

Other observations

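The tests in this part were chosen after the values had been seen. A set of 9 clones was 2-fold lower in both species at 7 d and 2-fold higher in both 35S::AtCBF3 columns, against 11.5 for independent lists. Their medians at 7 d were -1.76 in S. commersonii and -3.05 in S. tuberosum, and with 35S::AtCBF3 they were 5.04 and 3.37. Of the 9 clones, 5 were at least 8-fold higher in both transgenic columns. At 24 h all 9 were 2-fold lower in S. tuberosum (median -1.65), and 2 of the 9 in S. commersonii (median 0.13). The 5 clones lower in both species at 2 h had medians of 1.39 and 1.18 with 35S::AtCBF3, and 4 of the 5 were 2-fold higher in each transgenic column.

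S. tuberosum 35S::AtCBF3 was nearer to 7 d than to 24 h of cold, which S. commersonii 35S::AtCBF3 separated less: it correlated at 0.36 with 24 h and 0.35 with 7 d of its own cold response, and S. tuberosum 35S::AtCBF3 at 0.19 and 0.42 with the same S. commersonii columns. Against the S. tuberosum cold columns the values were 0.20 and 0.28 for S. commersonii 35S::AtCBF3, and 0.079 and 0.47 for S. tuberosum 35S::AtCBF3. The ratio of the correlations of S. tuberosum to those of S. commersonii was higher for 7 d than for 24 h by 0.68 (95% interval over clone-name blocks 0.60 to 0.77) with S. commersonii cold and by 1.29 (1.13 to 1.51) with S. tuberosum cold. The early clones alone are argued against, as the differences without them were 0.67 (0.56 to 0.77) and 1.04 (0.86 to 1.22). Noise in a transgenic column that is independent of the cold columns would lower its correlations with 24 h and 7 d by one factor. The differences of 0.68 and 1.29 therefore argue against such noise as the whole cause. A hypothesis is that the S. tuberosum lines may share more of the 7 d than of the 24 h response. Noise shared with a cold column, differences between the lines, the age of the plants and the slides were not tested and remain open.

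Clones that share the first 5 characters of their names were more alike than chance gives. Differences between these 157 blocks made up 5.53% of the variance at 7 d in S. commersonii and 5.43% in S. tuberosum, against at most 1.85% and 1.68% in 100 permutations of the names. At 2 h the shares were 2.46% and 3.41%.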
